A study of Mus musculus with 3 samples.

How the data were processed

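Monocytes from the pooled blood of 10 wild-type C57Bl/6 females were sorted into 3 subsets above 95% purity, per the labels, and total RNA of each was labelled with a whole-transcript expression kit and hybridised to 1 array. The deposited values are RMA values per probe set, per the submitters' processing notes, in the unit of intensity. RMA, the robust multi-array average, in its usual form corrects the background of each array, quantile normalizes the probes and summarizes each probe set by a median polish over the arrays. Its version, its settings, the level of summarization and the genome build are not given in the sources used here. The deposited intensity values ran from 2.22 to 7975 with 3 decimals and none was negative, so they were read as RMA values on a linear scale and turned into log2; that reading comes from the values and no label states it. No pseudocount was added, and no further normalization was applied for the values reported.

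The value table held 30177 probe sets. GEO's platform annotation, which can be old, gave 1 gene symbol to 21789 probe sets and several to 1621, and 6767 are unnamed here. Gene identifiers of 21698 of the named probe sets were found in a current RefSeq gene table, and no symbol changed through it. Probe sets with several symbols were not used to name a gene. For the 999 genes with several probe sets the one with the highest mean over the arrays was used, giving 19938 genes. A gene was kept where its log2 value reached the median of all probe sets on at least 1 array, which kept 9723 and left out 10215. Among genes left out, 3, 2 and 0 were at least 2-fold apart in the comparisons of Ly-6Clo TremL4+ with Ly-6Chi TremL4–, of both Ly-6Chi subsets and of both TremL4+ subsets. Among 4876 probe sets above the same filter that name no single gene, 19 were at least 2-fold higher and 80 lower in the first of these, 18 and 69 in the second and 35 and 29 in the third. No coordinates were used.

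Each subset had 1 array, so no p-value, standard deviation or standard error was computed. A difference is the log2 value on the first array minus that on the second, and genes were counted at 1 log2 unit, 2-fold, either way. The size was fixed before the data were examined, as were the gene lists, the comparisons and most alternatives. The arrays have no counts behind them, and their number limits the precision.

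Many values were identical between arrays. On at least 2 arrays 83.6% of probe sets had the same value to 3 decimals, and on all 3 arrays 60.7%, with 41.9% on at least 2 arrays in the brightest 10%. A difference of exactly 0 is read as a difference that was not resolved. A median polish can understate small differences: in a simulated median polish of 5000 probe sets of 11 probes with noise of 0.2 log2 units, a shift of 0.25 was read as 0.16 and a shift of 1 as 0.93. The number of probes and the noise were assumed.

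From general knowledge 23 gene lists and 9 lists of cell type markers were fixed. The gene lists were sort genes, Ly-6C high and Ly-6C low monocyte genes, monocyte transcription factors, S phase, G2 and M phase, interferon-stimulated genes, Toll-like receptors and their signalling, chemoattractant receptors, integrins and adhesion, Fc and scavenger receptors with complement, MHC class II and co-stimulation, MHC class I presentation, monocyte-derived dendritic cell genes, granule proteins, immediate early genes, cytokines and chemokines, apoptosis regulators, lipid handling, glycolysis, respiratory chain, ribosomal proteins and the TREM family. The markers were those of neutrophils, B cells, T cells, NK cells, platelets, erythroid cells, classical and plasmacytoid dendritic cells, and eosinophils with basophils, the cell types a blood sort could hold. The median difference of a list's kept genes was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was counted as standing apart under percentile 2.5 or above 97.5. By that definition 1.6 of 32 lists of randomly drawn genes would be counted if there were no ties, and 10, 9 and 10 were. Those counted include the sort genes and both monocyte lists, which the sort itself bears on, so the excess is no test. The percentile describes these arrays. Some lists share genes, so their places are not independent.

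Genes named are the 10 highest and 10 lowest kept genes of each comparison, the sort genes, and up to 4 kept members of each list with the largest difference either way. The middle array was the one with the middle of the 3 values, over genes spanning at least 2-fold, with an exact binomial interval. A gene with a tie had no middle array but stayed in the total. The position of the Ly-6Chi TremL4+ array was its difference from Ly-6Chi TremL4– divided by that of Ly-6Clo TremL4+, with a 95% interval of the median over genes.

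The steps were tested on simulated data for the comparison of Ly-6Clo TremL4+ with Ly-6Chi TremL4–, with 9723 genes and noise of 0.15 log2 units. All of 100 genes with a planted difference of 1.5 and all of 100 with 3 were recovered, and 0 unchanged genes were counted. Of 40 random lists 4 stood apart, a list of 25 genes shifted by 0.3 was at percentile 100, and a planted position of 0.5 was read as 0.505. No ties were planted, whereas 85.3% of the kept genes had the same value on at least 2 arrays. For the interferon-stimulated list, percentiles 2.5 and 97.5 of the matched random lists were both 0 in each comparison. There even a small median other than 0 could stand apart. The simulated lists therefore do not check the list percentiles under the ties of the data.

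Alternatives were no filter, a filter at the 75th percentile, a filter on the mean, centring on the median, quantile normalization, a loess on mean expression, the mean of a gene's probe sets, thresholds of 1.5-fold and 4-fold, other matching of the random lists, lists without shared genes, and stricter percentiles. The list mean in place of the median, and a list median of at least 0.1, were added after the data were seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.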

Results

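Gene expression was measured in 3 subsets of circulating monocytes from untreated wild-type C57Bl/6 female mice. Blood of 10 mice was pooled, and the cells were sorted on Ter-119, CD45.2, Ly-6G and CD115 as MHC-II low monocytes to a purity above 95%. Ly-6C is the surface protein that parts mouse monocytes into a classical Ly-6Chi and a patrolling Ly-6Clo population, and TremL4 is a receptor of the TREM-like family. The sort gave Ly-6Chi cells without and with the receptor (Ly-6Chi TremL4– and Ly-6Chi TremL4+) and Ly-6Clo cells with it (Ly-6Clo TremL4+), and RNA of each subset was hybridised to 1 whole-transcript microarray. There were no replicates, so no value below has an error and no difference has a test, and the number of arrays limits the precision of every comparison. Differences are log2 differences between single arrays, and the size that was counted is 2-fold.

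Each array held values for 30177 probe sets, with median intensities of 51.18 for Ly-6Chi TremL4–, 50.87 for Ly-6Chi TremL4+ and 51.03 for Ly-6Clo TremL4+. Across probe sets, which are not independent replicates, Pearson's r was 0.989 between both Ly-6Chi arrays, 0.992 between both TremL4+ arrays and 0.986 between Ly-6Chi TremL4– and Ly-6Clo TremL4+. Of 19938 genes, 9723 reached the median of all probe sets on at least 1 array and were compared. Many of these genes had exactly the same value on a pair of arrays, 66.9% of them in the comparison of Ly-6Clo TremL4+ with Ly-6Chi TremL4–, and such a 0 means that no difference was resolved.

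The genes of the sorting antigens were read first. Treml4 had log2 values of 5.72 on the Ly-6Chi TremL4– array, 7.66 on the Ly-6Chi TremL4+ array and 8.42 on the Ly-6Clo TremL4+ array, lowest in the subset sorted as negative for the receptor. Csf1r, which encodes CD115, had 8.46, 8.34 and 8.49 on the same arrays, and Ptprc, which encodes CD45, had 8.93 on all 3. Ly6g, the neutrophil antigen gated out, was below the filter with 5.28 on all 3. Ly6c1 and Ly6c2 were not analysed here, because no probe set named either of them alone.

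Ly-6Clo TremL4+ monocytes were compared with Ly-6Chi TremL4– monocytes to describe the far ends of the sort. Cd36, a scavenger receptor and fatty acid transporter, was 11.5-fold higher on the Ly-6Clo TremL4+ array (log2 8.12 against 4.59, a value below the filter, so the fold is not exact), and Treml4 was 6.50-fold higher. Slc12a2, a sodium-potassium-chloride cotransporter, was 6.07-fold higher, Fabp4, a fatty acid binding protein, 4.73-fold, and Fcgr4, an activating receptor for IgG, 4.70-fold. Chil3, a chitinase-like secreted protein, was 14.8-fold lower on the Ly-6Clo TremL4+ array (log2 5.44 against 9.32), as was Fn1, which encodes fibronectin (5.80 against 9.68). Ccr2, the chemokine receptor with which classical monocytes leave the bone marrow, was 7.79-fold lower, and F13a1, the A subunit of coagulation factor XIII, 7.62-fold lower. The dimmer values of Treml4, Fabp4, Fcgr4 and Fn1 lay not far above the filter, so these folds may not be exact either.

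In all, 104 of the 9723 genes were at least 2-fold apart between these arrays, 24 higher and 80 lower on Ly-6Clo TremL4+. The remaining genes among the 10 highest were Dusp16, a phosphatase of MAP kinases, at a log2 difference of 2.19, the adhesion receptor gene Adgre4 at 2.13, Smc6 at 1.98, the adaptor gene Stap1 at 1.95 and Ace, which encodes angiotensin-converting enzyme, at 1.87. Among the 10 lowest were also Wfdc17 at -3.15, the S100 family genes S100a10 at -2.56 and S100a6 at -2.43, the collagenase gene Mmp8 at -2.38, Emb at -2.29 and Ms4a4c at -2.29. Ms4a4c, Chil3, the S100a genes and Fcgr4 belong to families with close relatives, so their probes are open to cross-hybridisation.

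Gene lists for monocytes, fixed from general knowledge before the data were examined, lay on opposite sides. Of 20 Ly-6C high monocyte genes, 17 had a lower value on the Ly-6Clo TremL4+ array, 11 of them by at least 2-fold, and 1 a higher one, with a median difference of -1.19. Of 29 Ly-6C low monocyte genes, 25 had a higher value, 13 of them by at least 2-fold, and 1 a lower one, with a median of 0.80. Their medians were at percentiles 0 and 100 of 10000 random lists of the same size and mean expression, which describes these arrays and is no test. Below 2-fold on the Ly-6C low list were Nr4a1, the nuclear receptor required for Ly-6C low monocytes (7.56 against 6.98), the integrin gene Itgal (8.07 against 7.26) and Cd274 (6.65 against 5.83), which encodes PD-L1.

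Interferon-stimulated genes were lower on the Ly-6Clo TremL4+ array as a list: 26 of 27 had a lower value, and the median was -0.38 (percentile 0). Ifi27l2a was 2.84-fold lower, Trim30a 2.37-fold and Oasl2 2.14-fold, and no other member reached 2-fold. All 24 ribosomal protein genes had a lower value, with a median of -0.46 (percentile 0.1), where the central 95% of the matched random lists ran from -0.30 to 0.00. Rplp0 was 2.32-fold lower, and the other members stayed under 2-fold, except that Rps9 went from -0.91 to -1.08 with the mean of its probe sets. Their transcripts have many processed copies in the genome, so these probe sets too are open to cross-hybridisation.

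Smaller median differences were found for further lists, some of which lost their place under other choices. The 7 sort genes above the filter had a median of 0.16 (percentile 99.97), with 5 of them higher and only Treml4 by 2-fold. For 28 genes of the mitochondrial respiratory chain the median was -0.13 (percentile 0.01, but 5.89 with the list mean), with Cox4i1 2.01-fold lower and Cox6c 1.76-fold lower. The 15 genes for granule and antimicrobial proteins had a median of -0.16 (percentile 0.56, but 50 with no filter and 6.40 for the 6 genes on no other list), with Mmp8, Chil3, Hp at -1.59 and Lyz2, which encodes lysozyme M, at -1.02. Toll-like receptors and their signalling had a median of -0.10 over 18 genes (percentile 0.08, but 50 with no filter and 3.82 with the list mean), with Ly86 at -1.28 and Unc93b1, which carries nucleic acid sensing receptors to endosomes, at -0.78. The 22 Fc receptor, scavenger receptor and complement genes had a median of -0.18 (percentile 0, but 75.2 with the list mean of -0.03) and went both ways: Msr1 at -1.48 and Fcgr3 at -0.99 were lower, while Cd36 and Fcgr4 were among the highest genes of all. Beside the Ly-6C high and granule lists, the 6 neutrophil markers above the filter had a median of -0.11 (percentile 1.38) and stood apart under only 7 of the 12 alternatives that left it more than 1 gene, with percentiles up to 52.2. These included Mmp8 and Cd177 (-0.37), which the Ly-6C high and granule lists also hold, and Csf3r at -0.22.

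The MHC class I presentation list had a median of -0.08 (percentile 7.27, but 0.01 with random lists not matched on expression), with B2m at 0.22. The other lists had a median of 0.00, with percentiles from 49.6 to 60.5: monocyte transcription factors, S phase, G2 and M phase, chemoattractant receptors, integrins, MHC class II, monocyte-derived dendritic cell genes, immediate early genes, cytokines, apoptosis regulators, lipid handling, glycolysis, the TREM family, and markers of B, T and NK cells, platelets, erythroid cells, classical and plasmacytoid dendritic cells, and eosinophils and basophils. With the list mean, lipid handling (0.31, percentile 99.99), the TREM family (0.45, 99.88), integrins (0.08, 99.6) and MHC class II (0.10, 98.5) stood apart as higher and cytokines (-0.21, 1.49) as lower. This made 6 higher and 6 lower lists in place of 2 and 8. The TREM family list holds Treml4, the gene of a sorting antigen, at 2.70. Lipid handling shares Cd36, Fabp4 and Pparg with the Ly-6C low list. The 5 TREM family and 13 lipid genes on no other list had medians of 0.00 (percentiles 60.5 and 50.4). Their list means were not computed. Monocyte transcription factors stood apart as lower for the 13 genes on no other list (-0.07, percentile 0.45). Single members stood out within the lists with a median of 0.00. S1pr5, a sphingosine-1-phosphate receptor, was 2.08-fold higher on the Ly-6Clo TremL4+ array, the tetraspanin gene Cd9 2.94-fold, Eno3, a muscle-type enolase, 2.59-fold and Pparg, a lipid-sensing nuclear receptor, 2.11-fold. Tgfbi was 3.96-fold lower, the chemokine gene Ccl9 2.76-fold and Npc2, a lysosomal cholesterol carrier, 3.18-fold.

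For Cox4i1 and Lyz2 the difference dropped under 2-fold when the arrays were quantile normalized, to -0.88 and -0.83, and for the Ly-6C high list gene Plac8 (-1.24) to -0.98. Of 13 further probe sets of genes counted here, 8 went the same way, 7 of them by at least 2-fold, and on their dimmer array 8 of the 24 higher and 17 of the 80 lower genes lay below the median of all probe sets (5.68 on Ly-6Chi TremL4–, 5.67 on Ly-6Clo TremL4+), among them Cd36, Slc12a2, Stap1, Dusp16, Chil3, Mmp8 and F13a1, whose folds are therefore not exact.

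**Figure D1:**
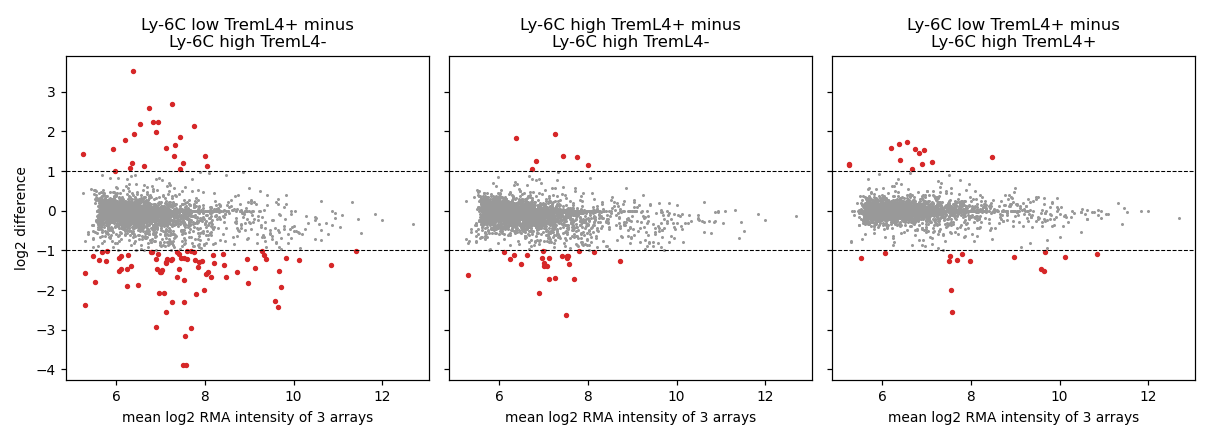
Log2 difference of each of the 9723 genes against its mean log2 RMA intensity over the 3 arrays, for each pair of arrays, 1 array per subset. Points past the dashed lines, in red, are genes at least 2-fold apart: 104 between Ly-6Clo TremL4+ and Ly-6Chi TremL4–, 33 between the Ly-6Chi subsets and 28 between the TremL4+ subsets.

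Ly-6Chi TremL4+ were then compared with Ly-6Chi TremL4– monocytes, which share the Ly-6C gate and differ in the receptor. Treml4 was 3.85-fold higher on the TremL4+ array (log2 7.66 against 5.72) and Cd36 3.55-fold higher (6.42 against 4.59). Ace was 2.60-fold higher, Adgre4 2.57-fold, the MHC class II gene H2-Ab1 2.37-fold, Ceacam1, an adhesion receptor of the immunoglobulin superfamily, 2.21-fold and Slc12a2 2.06-fold. Fn1 was 6.14-fold lower on the TremL4+ array (7.06 against 9.68), F13a1 4.22-fold, S100a10 3.30-fold and Ccr2 3.29-fold.

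These 7 higher genes and 26 lower ones made up the 33 genes at least 2-fold apart. Just below 2-fold among the 10 highest were Pglyrp1, a peptidoglycan recognition protein, at 0.97, H2-Aa at 0.87 and Dnah7b at 0.85. The remaining genes among the 10 lowest were Emb at -1.70, Mmp8 at -1.61, Ifi209 at -1.40, Gstm1, a glutathione transferase, at -1.39, Chil3 at -1.34 and Ly6a2 at -1.33. Ifi209, Gstm1 and Ly6a2 have near-identical relatives and are open to cross-hybridisation.

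H2-Aa, H2-Ab1, H2-Eb1 and Cd74, 4 genes of MHC class II presentation, were higher on this array than on both others. H2-Aa had 7.25 against 6.38 on each of the other arrays, H2-Ab1 7.48 against 6.24 on Ly-6Chi TremL4– and 6.74 on Ly-6Clo TremL4+, Cd74, the invariant chain, 7.21 against 6.41 and 6.60, and H2-Eb1 6.67 against 6.30 and 6.45. H2-DMa did not share this, with 6.07 against 6.52 and 6.04. The list of MHC class II and co-stimulation genes as a whole had a median of 0.00 over 13 genes (percentile 50.6), but stood apart as higher with the list mean (0.23, percentile 100), with a filter at the 75th percentile (0.41, percentile 100) and with a loess (percentile 98.8). The list of sort genes, which holds H2-Aa, H2-Ab1, H2-Eb1 and Cd74, had a median of 0.80 over 7 (percentile 100). Of the B cell markers, which could bring such transcripts, Cd79a had 6.19 against 6.08 and 5.96, and the marker list had a median of 0.00 over 4 genes (percentile 50.2). The 12 classical dendritic cell markers, 4 of them these MHC genes, had a median of 0.00 (percentile 51.3), but a mean of 0.23 (percentile 100) and, with a filter at the 75th percentile, a median of 0.59 over 6 genes (percentile 100).

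Both monocyte lists already differed between the Ly-6Chi subsets. Of 20 Ly-6C high monocyte genes, 18 had a lower value on the TremL4+ array, 7 by at least 2-fold, with a median of -0.76 (percentile 0). Of 29 Ly-6C low monocyte genes, 23 had a higher value, 4 by at least 2-fold, with a median of 0.38 (percentile 100). The interferon-stimulated list had a median of -0.31 (percentile 0), with 23 of 27 genes lower and none by 2-fold; Trim30a was at -0.89, Ifit1 at -0.76 and Xaf1 at -0.72. Ribosomal protein genes had a median of -0.41 (percentile 0.02), with 23 of 24 lower and Rplp0 at -0.80.

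Lower medians past the percentile limits were also found for the granule list (-0.14, percentile 1.17), with Cybb, a subunit of the phagocyte oxidase, at -0.88, and for Toll-like receptor genes (-0.06, percentile 0.42), with Tlr8 at -0.69. Both lost their place with no filter (percentile 50), the granule list also for its 6 genes on no other list (9.04) and the Toll-like receptor genes with a filter at the 75th percentile (5.15). Fc and scavenger receptors had a median of -0.11 (percentile 0.01, but 15.9 with the list mean), with Fcgr3 at -0.84, and the respiratory chain -0.10 (percentile 0.05, but 3.18 with the list mean), with Atp5b at -0.59. Neutrophil markers had a median of -0.07 (percentile 3.22, but 0.49 with the list mean of -0.34). MHC class I genes had -0.07 (percentile 9.37, but 0 with random lists not matched on expression). All other lists had a median of 0.00, where the TREM family (0.27, percentile 99.94) and lipid handling (0.09, 99.6) stood apart as higher with the list mean, and monocyte transcription factors as lower for the 13 genes on no other list (-0.14, percentile 0.07). The TREM family list holds Treml4, on which these subsets were sorted. Its 5 genes on no other list had a median of 0.00, as had the 13 such genes of lipid handling. Among members of the cytokine and platelet lists, whose medians were 0.00, Ccl9 was 2.21-fold lower on the TremL4+ array. Ccl9 is also on the Ly-6C high list. The platelet chemokine gene Ppbp had 6.71 on the TremL4+ array against 6.21.

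Quantile normalization took Wfdc17 from -1.14 to just under 2-fold, and it took Pglyrp1 from 0.97 to 1.02. On their dimmer array Cd36, Slc12a2 and Mmp8, 3 of the 33 genes, lay below the median of all probe sets, so their folds are not exact. Treml4 lay only a little above that median on Ly-6Chi TremL4–, so its fold may not be exact either.

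**Figure D2:**
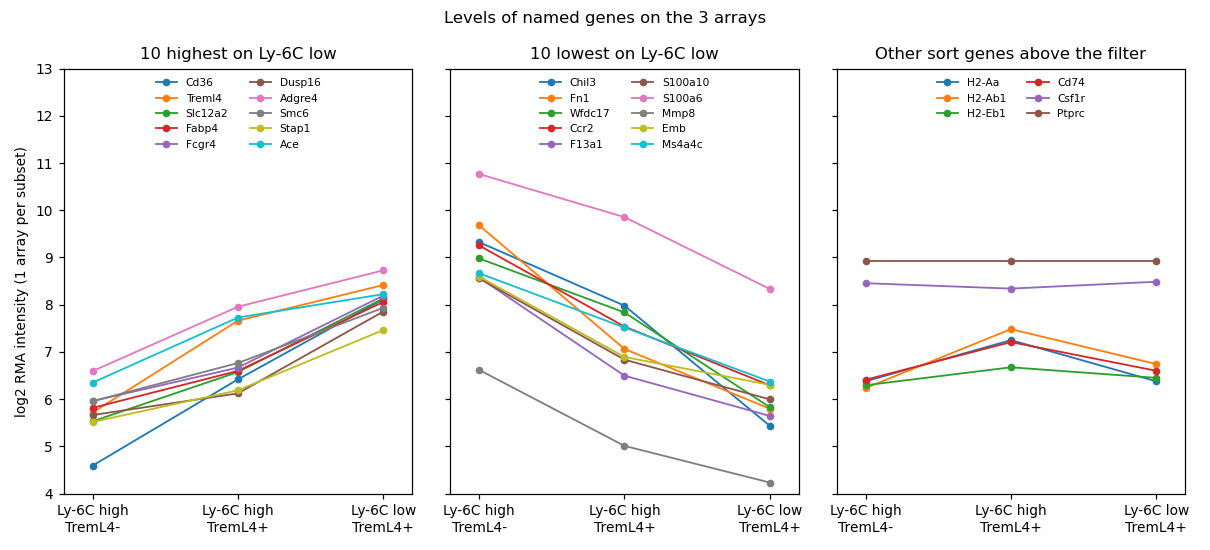
Log2 RMA intensity of named genes on the 3 arrays, 1 array per subset, joined by lines to follow each gene and not to show an order in time. The left and middle panels hold the 10 highest and 10 lowest genes on Ly-6Clo TremL4+ against Ly-6Chi TremL4–, and the right panel holds sort genes above the filter, where H2-Aa, H2-Ab1, H2-Eb1 and Cd74 are highest on Ly-6Chi TremL4+ and Ptprc is at 8.93 on all 3.

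Ly-6Clo TremL4+ and Ly-6Chi TremL4+ monocytes share the receptor and differ in Ly-6C. Dusp16 was 3.32-fold higher on the Ly-6Clo array (log2 7.86 against 6.12), Cd36 3.24-fold (8.12 against 6.42), Sh2d1b1, an adaptor of SLAM family receptors, 3.01-fold, Slc12a2 2.94-fold and Fcgr4 2.87-fold. Treml4 itself was 1.69-fold higher. Chil3 was 5.83-fold lower on the Ly-6Clo array (5.44 against 7.98), Wfdc17 4.02-fold, S100a6 2.87-fold, Crip1 2.78-fold and Fn1 2.40-fold.

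Between these arrays 28 genes were at least 2-fold apart, 13 higher and 15 lower on Ly-6Clo. The 10 highest also held Fabp4 at 1.46, Hpgd, which degrades prostaglandins, at 1.35, Stap1 at 1.28, Cd300ld at 1.22 and Bcl2a1c at 1.18; Cd300ld and Bcl2a1c have near-identical relatives. The 10 lowest also held Tgfbi at -1.26, Ccr2 at -1.24, Ifi205 at -1.20, Plac8 at -1.17 and Vim, which encodes vimentin, at -1.16. Hpgd had its lowest value on the Ly-6Chi TremL4+ array, 7.87 against 8.32 on Ly-6Chi TremL4–.

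Of 20 Ly-6C high monocyte genes, 17 had a lower value on the Ly-6Clo array, 4 by at least 2-fold, and 1 a higher one, with a median of -0.41 (percentile 0). Of 29 Ly-6C low monocyte genes, 24 had a higher value, 7 by at least 2-fold, and none a lower one, with a median of 0.37 (percentile 100). Interferon-stimulated genes had a median of -0.10 (percentile 0), with 20 of 27 lower and Ifi27l2a 2.04-fold lower. Ribosomal protein genes had a median of -0.13 (percentile 0.04), with 19 of 24 lower, and lost that place when the list mean was used (percentile 8.78). The sort genes had a median of -0.22 (percentile 0.06), with H2-Aa at -0.87, H2-Ab1 at -0.74 and Cd74 at -0.61.

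Small medians past the percentile limits were those of classical dendritic cell markers (-0.07, percentile 0), which hold the same MHC class II genes, neutrophil markers (-0.04, percentile 0.93), MHC class II and co-stimulation (-0.01, percentile 0.02) and the granule list (-0.01, percentile 0.66). The last 3 lost their place with no filter, and the last 2 also for their 6 genes on no other list (percentiles 49.8 and 6.49). The Fc and scavenger receptor list had a median of -0.04 (percentile 0, but 50 with no filter) and a mean of 0.08 (percentile 98.8), so its median and mean differed in sign; Cd36 and Fcgr4 were higher and Msr1 was at -0.86. Respiratory chain, Toll-like receptor and MHC class I genes, and all other lists, had a median of 0.00, and with the list mean lipid handling (0.22, percentile 100), the TREM family (0.18, 98.7) and integrins (0.08, 99.6) stood apart as higher and cytokines (-0.08, 2.13) as lower. Lipid handling shares Cd36, Fabp4 and Pparg with the Ly-6C low list, and the TREM family list holds Treml4. Their 13 and 5 genes on no other list had medians of 0.00. Because most genes were tied between these arrays, random lists also had medians at or near 0, and only 4 of the 10 lists past the percentile limits had a median of at least 0.1 either way: both monocyte lists, the ribosomal proteins and the sort genes. Of the 28 genes, Chil3, Ifi205, Lilra6, Bcl2a1c and Olfr521 lay below the median of all probe sets on their dimmer array, so their folds are not exact. Fn1 lay not far above that median on the Ly-6Clo array.

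**Figure D3:**
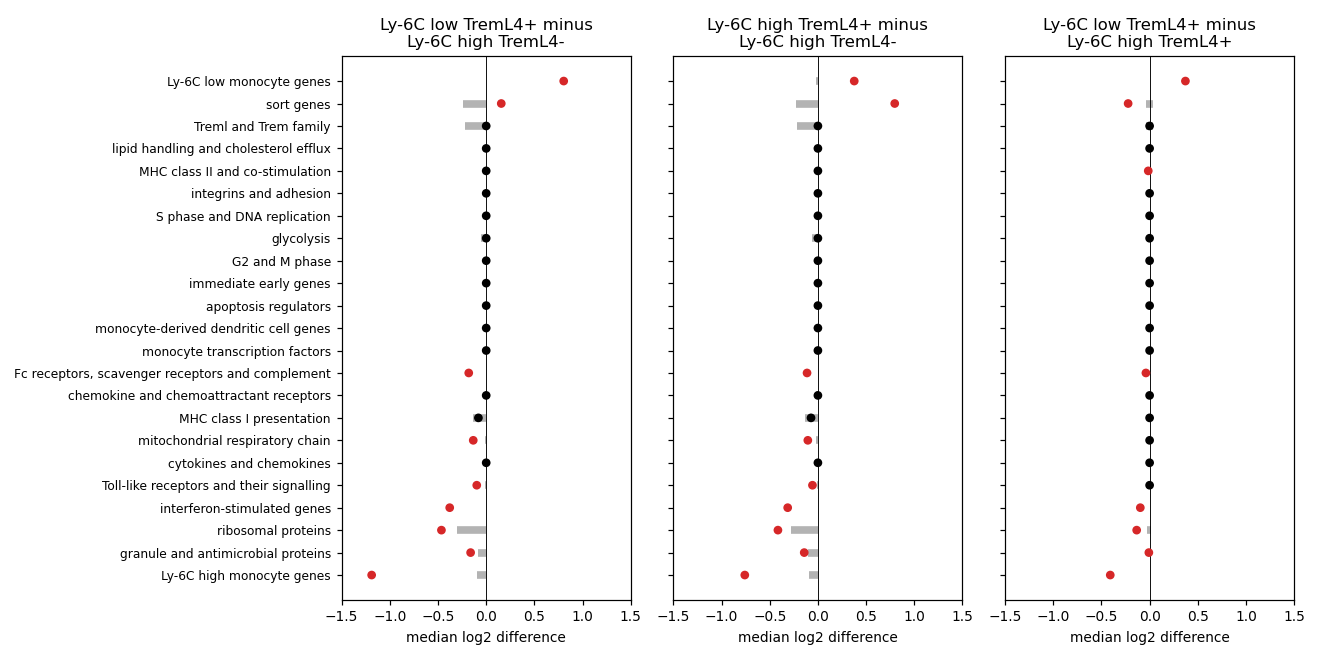
Median log2 difference of each of the 23 gene lists in each comparison, as points, with a grey bar for the central 95% of 10000 random lists of the same size and mean expression. Red points are outside that range; the Ly-6C high list is at -1.19, -0.76 and -0.41 and the Ly-6C low list at 0.80, 0.38 and 0.37 from left to right.

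The 3 arrays were last read together, to ask whether the Ly-6Chi TremL4+ array lay between the other arrays. Among 110 genes whose values spanned at least 2-fold, it held the middle value for 104 (94.5%, exact 95% binomial interval 88.5 to 98.0 over genes), and each of the other arrays for 3 (2.73%). Exchangeable arrays would give 33.3% each, and genes are not independent, so the interval covers counting error only. These shares leave out the 4876 probe sets above the filter that name no single gene. Of those, 35 were at least 2-fold higher on Ly-6Clo TremL4+ than on Ly-6Chi TremL4+, but only 19 than on Ly-6Chi TremL4–. Some of them were therefore lowest on Ly-6Chi TremL4+, and the middle share is not shown for them.

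A position between both ends was taken for each of the 104 genes at least 2-fold apart between them, where 0 is the Ly-6Chi TremL4– value and 1 the Ly-6Clo TremL4+ value. The median position was 0.603 (95% interval over genes 0.530 to 0.650), and noise alone would centre it on 0.5. The interval is no test against 0.5, because all genes come from the same single arrays and are not replicates. An offset of 1 array would move many of them together, and quantile normalization alone gave 0.549. The 80 genes lower on Ly-6Clo TremL4+ had a median position of 0.635 (0.571 to 0.672) and the 24 higher genes 0.405 (0.318 to 0.599), but 0.518 over 49 higher genes at 1.5-fold, past the midpoint. Under quantile normalization the lower genes were at 0.579 and the higher genes at 0.459. A part of this gap may therefore come from the scaling of the arrays, and no order of loss and gain is read from it. On their dimmer end 8 of the 24 and 17 of the 80 genes lay below the median of all probe sets, so their positions are not exact. Plac8 at 0.0555 and Sh2d1b1 at 0.103 had nearly the Ly-6Chi TremL4– value on the middle array, and Fn1, F13a1, S100a10 and Treml4 lay nearer to the Ly-6Clo TremL4+ value, as their differences above show. With genes at least 4-fold apart the median position was 0.518 over 21 genes.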

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

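The list mean in place of the median and a list median of at least 0.1 were chosen after the data were seen. No paired analysis was possible because each subset had 1 array. Other filters, scalings and probe set rules at the 2-fold size gave 95 to 107 genes for Ly-6Clo TremL4+ against Ly-6Chi TremL4–, 30 to 35 for the Ly-6Chi pair and 25 to 29 for the TremL4+ pair, a middle share of 93.1 to 95.2% and a median position of 0.549 to 0.614. Under quantile normalization the position was 0.579 for lower and 0.459 for higher genes. The size threshold set the counts by construction. At 1.5-fold they were 280 (49 higher, 231 lower), 180 (23 and 157) and 75 (27 and 48), and at 4-fold 21 (7 and 14), 2 and 2. The middle share was 80.0% of 310 genes at 1.5-fold and 100% of 21 at 4-fold, and the position at 4-fold was 0.518. Tied genes, 0 of the 110 at 2-fold, count against the share. Their number at 1.5-fold was not recorded, so part of the fall to 80.0% may be ties. The cause was not tested further. For the TremL4+ pair, 10 lists stood apart, but 6 with no filter; the cause was not tested. With a median of at least 0.1 there were 4, since the other medians were nearer to 0. Without sort genes and genes on other lists there were 5, where the sort genes were not run and other lists had lost members; the cause was not tested further. The Ly-6C high and Ly-6C low lists stood apart in every comparison under all 13 alternatives. The granule list stood apart under 10, 10 and 8 of 13 alternatives in the 3 comparisons in this order, Toll-like receptors under 10 in each of the first 2, and neutrophil markers under 7 in the first and the last; the cause was not tested. Without genes on other lists the neutrophil and classical dendritic cell lists held 1 gene each, so that alternative says nothing about them. Higher and lower lists numbered 2 and 8, 2 and 7, and 1 and 9 with the median, and 6 and 6, 6 and 6, and 5 and 8 with the list mean. A filter at the 75th percentile gave 6 and 7, 6 and 6, and 3 and 9. With the list mean, the respiratory chain was at percentile 5.89 for Ly-6Clo TremL4+ against Ly-6Chi TremL4– and 3.18 for the Ly-6Chi pair, and the Fc and scavenger receptors at 75.2 and 15.9. Of 3516 single gene differences recomputed, 3503 kept their side of 2-fold, 13 crossed it, and 0 of those past 2-fold reversed. Of 91 named differences of at least 2-fold, 5 dropped below it under some alternative: those of Cox4i1, Lyz2, Plac8, Wfdc17 and Dnah7b, the last to 0.58 with the mean of its probe sets. Hpgd and Rps9 for Ly-6Clo TremL4+ against Ly-6Chi TremL4– and Pglyrp1 for the Ly-6Chi pair went past it. Signal over background was not analysed here beyond the filter.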

Other observations

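The tests on B cell and dendritic cell markers, and the use of an interval over genes for the scaling tests, were chosen after the results were seen. Genes outside the naming rule in this part were also chosen after their values were seen.

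Cx3cr1, the fractalkine receptor and a marker of Ly-6C low monocytes, showed no resolved difference, with the same log2 value of 7.73 on all 3 arrays. Cell cycle genes were mostly below the filter: 12 of 30 measured S phase genes and 8 of 30 measured G2 and M phase genes were kept, and none was 2-fold apart. Genes of the TREM family other than Treml4 included Trem3, at 5.26 on Ly-6Chi TremL4–, 5.61 on Ly-6Chi TremL4+ and 6.16 on Ly-6Clo TremL4+, and Tyrobp, an adaptor of TREM receptors, at 10.91, 10.65 and 10.62 on the same arrays.

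Few of the 9723 genes, most of them tied between arrays, put the Ly-6Chi TremL4+ array outside both others by at least 0.5 log2 units. Smaller margins were not counted. Among 310 genes spanning at least 1.5-fold it held the middle value for 248, and ties among the rest were not separated. Only H2-Aa, H2-Ab1 and Cd74 lay above both by at least 0.5 log2 units, by 0.87, 0.74 and 0.61. Below both by that much lay 6 genes: Rbm12b2, Olfr521, Snord57, Slc10a4, Zfp600 and Tnpo1. Probe sets that name no single gene were not counted here, and some of them were lowest on this array. Cells were gated as MHC-II low, and B cells or classical dendritic cells in this sample could bring MHC class II transcripts. Of 4 B cell markers above the filter outside the MHC genes, 1 had a resolved difference (Cd79a, 0.17 above the mean of the other arrays), and Cd79b, Cd22 and Vpreb3 were tied. Of 7 classical dendritic cell markers, 4 had a resolved difference, with Naaa at -0.13 and 0 above both other arrays. Too few markers were resolved to set either source aside, since ties can hide a small share of cells, and higher MHC class II expression in these monocytes stays open and untested.

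Identical values on several arrays may come from the median polish over 3 arrays. In a simulation with assumed noise, 84.0% of probe sets without a difference were tied on 2 arrays or more with 11 probes, and 97.1% with 25. On all 3 arrays 43.7% and 78.5% were tied. The data had 83.6% and 60.7% over all probe sets, changed ones included. The simulated shares hang on the assumed probe number, so their closeness to the data is not read as a match. Leaving out probe sets identical on all 3 arrays, ties in the data decreased from 76.7% at spans up to 0.25 log2 units to 1.81% at spans over 1. Such a decrease could also come with other causes of ties, so it does not single out the polish. Simulated values with independent noise, rounded to 3 decimals, were tied in 0.0133% of probe sets, which argues against rounding. Other steps of the submitters' processing were not tested, and no biological explanation was tested.

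More genes were lower than higher on Ly-6Clo TremL4+ against Ly-6Chi TremL4–, 80 of 104 (76.9%). A candidate explanation is the scaling of bright probe sets, since the 99th percentile of log2 values was 10.13 on Ly-6Chi TremL4– and 9.96 on Ly-6Clo TremL4+. After a loess on mean expression 72.0% of the genes apart were lower (exact 95% interval over genes 62.1 to 80.5), and after quantile normalization 70.5% (60.3 to 79.4). Both intervals lie above the 60% that scaling as the whole cause would allow, for quantile normalization narrowly and with genes taken as independent, but both hold 70%, the share set beforehand for putting scaling aside, so a part from scaling stays open. A difference between the subsets also stays open, and 1 array per subset cannot separate it from a difference between arrays.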
